A study of Homo sapiens with 2 samples.

How the data were processed

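Total RNA from PANC-1 cells with shCtrl or shWBSCR22 was made into sequencing libraries with an Illumina TruSeq RNA kit, per the labels' protocols, with 1 library per group and 2 in all. The submitters' processing notes name bcl2fastq, FastQC, HISAT2, StringTie and DESeq, with GRCh38 as the genome build, and give no versions, roles or order. The annotation release, the program that counted reads, the use of strand, any removal of duplicate reads and the scaling behind the FPKM values are not given in the sources used here. The authors deposited a table of raw counts per gene and a table of FPKM per gene, with gene identifiers, symbols and coordinates. Counts were whole numbers with a different total in each library, 16121638 in shCtrl and 15248099 in shWBSCR22. The deposited FPKM were 0 exactly where the count was 0. Of 20981 gene identifiers 20951 were found in GENCODE release 29 and 20570 had the same coordinates there. GENCODE release 29 transcripts gave the GC content, and printed coordinates are those of the deposited table. In shCtrl 4354 genes and in shWBSCR22 5954 had 0 counts, and 2961 had 0 in both.

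Groups were taken from the treatment in the labels. Genes with a mean of at least 1 CPM over the libraries were kept (12980). Counts were scaled by TMM (edgeR 4.0.16 in R 4.3.3), and the log2 ratio of shWBSCR22 over shCtrl was taken with 0.5 counts added to each library. The normalization factors were 1.03 and 0.971. The counting interval was the exact conditional binomial (Clopper-Pearson) 95% interval of the ratio. A gene was called higher or lower where its log2 ratio was at least 1 in size and this interval excluded 0. No p-value was computed, because 1 library per group leaves no residual degrees of freedom and genes are not replicates. Folds against a library with 0 counts were computed against 3 counts in that library. Reads without molecular identifiers are not independent molecules, so intervals and these bounds cover counting error only. A wider interval, chosen after the data were seen, divided the counts by 8 in shCtrl and 15 in shWBSCR22, the most frequent low counts of each library after averaging over 3 neighbouring counts, before the same formula. Genes that share reads with near-identical copies or overlap on opposite strands are uncertain, since the treatment of shared reads and of strand is not given in the sources used here.

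Before the data were examined, 44 gene lists of pathways, complexes and cell type markers were fixed, with 1246 entries, of which 1053 were measured. Each list was described by its median log2 ratio with a binomial order-statistic 95% interval, by its members called higher, lower or neither, and, with at least 5 measured members, by the percentile of its median among 10000 random lists of the same size matched on 20 bins of mean expression. A list was said to stand apart under percentile 2.5 or over 97.5. Percentiles with matching on GC content as well were added with 10 GC bins, as were percentiles among genes of at least 30 CPM. The lists covered BUD23 and TRMT112 partners, interferon-stimulated, RNA and DNA sensing, NF-kB and MHC class I genes, mitosis, DNA replication, G1 regulators, ribosome assembly, RNA polymerase I, ribosomal proteins, mitochondrial ribosome, oxidative phosphorylation, mitochondrial transcripts, p53, stress, heat shock, proteasome, lipid synthesis, hypoxia, mesenchymal, epithelial, invasion, growth factor signalling, NRF2, glucocorticoid, metallothionein, apoptosis, autophagy, histone, Williams-Beuren, small RNA and reference genes, and markers of acinar, ductal, endocrine, fibroblast, endothelial and leukocyte cells.

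Named genes followed a rule fixed before the data were examined: BUD23, TRMT112, ISG15 and PLAGL1, the latter ones because published work ties them to BUD23; the 10 genes higher and 10 lower with the counting-interval bound farthest from 0, leaving out symbols that are clone names, long noncoding or antisense; up to 4 members of each list with the largest absolute log2 ratio, and 10 of the interferon list; and the gene with the highest share of counts. IFIT1, EIF2AK2, CDKN2A, RRP9, DCAF13, PDCD11, STX1A, DNAJC30, TMEM238, SLC29A4, CLIC3, MPO and the genes named only in the closing observations were chosen after their values were seen. Some genes that the rule selects are not reported here.

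The procedure was tested on simulated data, with counts for shWBSCR22 against shCtrl drawn from the mean profile and 200 genes changed. With reads drawn one by one over 12979 genes, the rule with the counting interval recovered 96.8% of genes changed 3-fold and 100% of those changed 6-fold, and called 37 unchanged genes. With reads drawn in groups of 8 and 15 over 12973 genes, it recovered 79.2% and 97.9% and called 2083 unchanged genes, and the wider interval recovered 66.7% and 86.2% and called 219. Alternatives were total-count, DESeq2 (1.42.0) and upper-quartile scaling, 2 counts added before the log, deposited FPKM with pseudocounts of 0.1 and 1, other filters on low counts and other size rules, and, added later, the wider interval, a mean of at least 30 CPM, subtraction of the median of each GC bin and the interferon list without ISG15. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used.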

Results

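Messenger RNA was sequenced from cells labelled PANC-1, an established human cell line derived from a carcinoma of the pancreatic duct. The identity of the cells was taken from the labels and was not tested. The cells carried either a control short hairpin RNA (shCtrl) or a hairpin against WBSCR22 (shWBSCR22). WBSCR22 is the older symbol of BUD23, a methyltransferase that modifies the RNA of the small ribosomal subunit and works with the cofactor TRMT112. Each group held 1 library. The deposited counts summed to 16121638 reads in shCtrl and 15248099 in shWBSCR22, over 20981 listed genes, of which 12980 had a mean of at least 1 CPM, the count scaled to the library total, and were compared. The most abundant transcript in both libraries was MT-CO2, a mitochondrial subunit of cytochrome oxidase, with 2.10% and 2.07% of the counts. With 1 library per group no difference below has a replicate check, so every value compares these libraries and not the conditions.

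The comparison of shWBSCR22 with shCtrl addresses how the transcriptome of these cells differs when BUD23 is targeted, and the targeted gene was examined first. BUD23 (ENSG00000071462, chromosome 7, 73683025 to 73705161, plus strand, GRCh38) had 3487 counts in shCtrl and 1892 in shWBSCR22, or 27.1 and 15.6 FPKM. Its log2 ratio after scaling was -0.72, which is 39.1% lower, with a 95% counting interval of -0.80 to -0.63. It lay in the direction the label names and short of the 2-fold difference set as the size rule. Of 1355 genes at a similar level, between 0.5 and 2 times the mean CPM of BUD23 and itself included, 3.76% had a lower log2 ratio. TRMT112 (chromosome 11, 64316460 to 64318084), its cofactor, had 4051 and 2451 counts and a log2 ratio of -0.56 (-0.63 to -0.49). Of 1187 genes at a level similar to TRMT112, itself included, 7.16% had a lower log2 ratio. PLAGL1, a zinc-finger transcription factor, had 114 and 86 counts and a log2 ratio of -0.24, with an interval of -0.66 to 0.18 that held 0. BUD23 overlaps the start of DNAJC30 and part of STX1A, both on the other strand; these had log2 ratios of -0.26 and -0.01.

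Low counts were not spread as counting error alone would spread them. The number of genes per count peaked at 8 reads in shCtrl and at 15 in shWBSCR22, and 210 genes had at least 41 counts in one library and 0 in the other. A wider interval was therefore added after the data were seen, made from counts divided by 8 and 15 reads. It ran from -1.01 to -0.43 for BUD23 and from -0.82 to -0.30 for TRMT112, and both excluded 0. For PLAGL1 it ran from -1.94 to 1.24. Of 17 common reference genes, this interval lay above 0 for 4 and below 0 for 4, among the latter GAPDH (log2 ratio -0.83) and ACTB (-0.65). Excluding 0 therefore does not by itself set BUD23 or TRMT112 apart. The counting intervals and this wider interval both cover the error of drawing reads and say nothing of the difference between cultures. Where an interval follows a gene's log2 ratio below without a name, it is the wider one, and after a list's median it is the order-statistic interval.

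**Figure D1:**
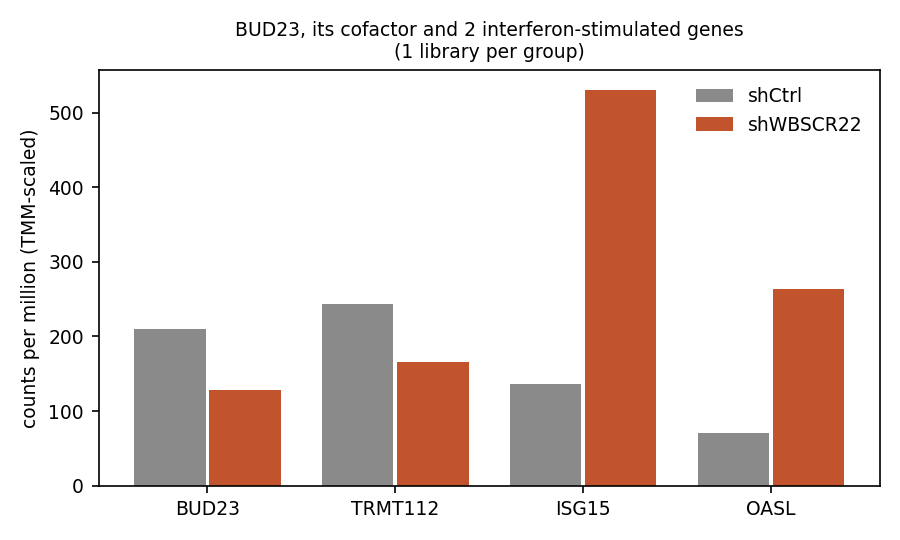
TMM-scaled CPM (linear axis) of BUD23, TRMT112, ISG15 and OASL in the shCtrl (grey) and shWBSCR22 (orange) libraries, 1 library per group and so without error bars. BUD23 and TRMT112 stood lower in shWBSCR22, with log2 ratios of -0.72 and -0.56, and ISG15 and OASL higher, with 1.95 and 1.89.

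ISG15, a ubiquitin-like modifier induced by type I interferon, was 3.88-fold higher in the shWBSCR22 library. Published work on pancreatic cancer cells placed it downstream of BUD23. Whether that work drew on these same libraries was not known here, so the value is no independent check of it. ISG15 (ENSG00000187608, chromosome 1, 1001138 to 1014541, plus strand) had 2271 counts in shCtrl and 7848 in shWBSCR22, or 149 and 544 FPKM, and a log2 ratio of 1.95 with a counting interval of 1.89 to 2.02 and a wider one of 1.74 to 2.17. Of 847 genes at a similar level, itself included, 0 had a higher ratio. OASL, an antiviral relative of the oligoadenylate synthetases, went from 1175 to 3893 counts between the libraries (log2 ratio 1.89, 1.60 to 2.20), and IFITM1, a membrane protein that blocks viral entry, from 274 to 662 (1.44, 0.76 to 2.13).

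Of 50 type I interferon stimulated genes fixed as a list, 38 were measured, of which 8 were higher, 3 lower and 27 neither by the size rule. With the wider interval 3 were higher, ISG15, OASL and IFITM1, and 0 lower. Leaving the size of the ratio aside, that interval lay above 0 for 8 members and below 0 for 1, EIF2AK2 (-0.66, -1.34 to -0.04). The list's median log2 ratio was 0.44, with an order-statistic interval of 0.0019 to 0.69, and lay at percentile 99.88 among 10000 random lists matched on expression, which describes these libraries only. Further members called higher with the counting interval alone were DHX58, IFI44, OAS1 and IFIT1, with log2 ratios of 1.71, 1.70, 1.43 and 1.07 and at most 85 counts in either library. IFIT2, an interferon-induced RNA-binding protein also called with that interval alone, had 1 and 31 counts (4.56, counting interval 2.54 to 10.47). PARP9, IFIT5 and IFI27 were the 3 called lower, with -1.90, -1.79 and -1.35, and their wider intervals held 0. Among 10 members with a mean of at least 30 CPM the median was 0.63, at percentile 99.93. When every gene with at least 1 count was taken in, 46 members had a median of 0.13 at percentile 86.92, so the list then no longer stood apart. Genes that sense double-stranded RNA or DNA ahead of interferon had a median of -0.22 over 19 measured members (percentile 13.98); JAK1, a kinase of the interferon receptor, was higher (1.27, 0.19 to 2.38).

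Over all 12980 genes, 1586 were higher and 1546 lower in shWBSCR22 by the size rule with the counting interval. Total-count scaling gave 1433 and 1747, and the deposited FPKM with a pseudocount of 0.1 gave 1244 and 1508, so the balance turned towards lower. With the wider interval the counts were 544 and 387. The share of all genes called was 24.1% with the counting interval and 7.17% with the wider one. Counts of list members called higher or lower below use the counting interval, unless the wider one is named. Among 3803 genes with a mean of at least 30 CPM, 123 were higher and 67 lower with either interval. In simulated libraries with reads drawn in groups of 8 and 15, the size rule called 2083 unchanged genes with the counting interval, 219 with the wider one, and 0 with a mean of at least 30 CPM. The spread of log2 ratios, as an SD across genes, was 2.34 at 1 to 5 CPM and 0.442 above 100 CPM. Drawing reads in groups of 8 and 15 would alone give about 1.15 and 0.119. The simulation gave unchanged genes only this smaller spread, which at 30 CPM or more is small against a log2 ratio of 1. Its numbers of unchanged genes called, the 0 included, therefore set no rate of false calls for the observed libraries.

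**Figure D2:**
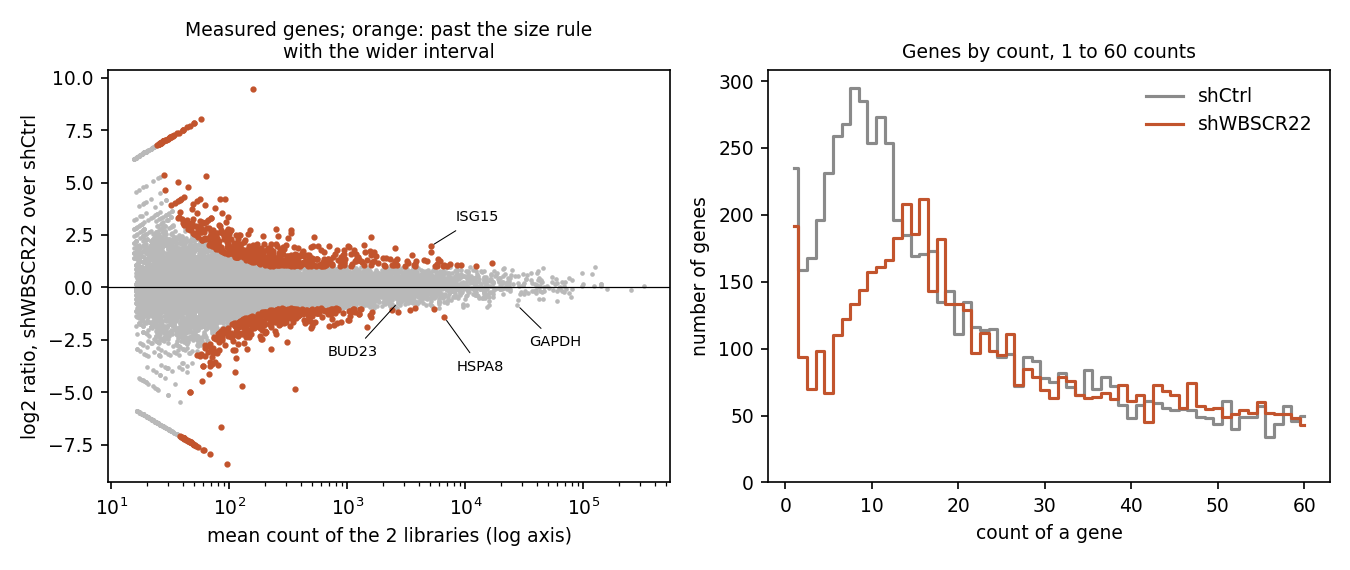
Left, log2 ratio of shWBSCR22 over shCtrl against the mean count (log axis) of each of 12980 measured genes, with genes past the size rule with the wider interval in orange. Right, number of genes at each count from 1 to 60 in the shCtrl (grey) and shWBSCR22 (orange) libraries, which peak at 8 and 15 reads when averaged over 3 neighbouring counts.

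The 10 genes highest in shWBSCR22 by the counting-interval bound all had 0 counts in shCtrl, so their folds are computed against a floor of 3 counts. These folds take each read as independent, and the bound of the wider interval, which is far nearer 0, is given beside them. USH1C, a scaffold protein of the brush border and of hair cells, had 314 counts, at least 117-fold higher against the floor, with a log2 ratio of 3.45 at the lower bound of the wider interval. LRG1, a secreted glycoprotein, had 115 (at least 43.0-fold against the floor, lower bound 1.77), MZB1, an endoplasmic reticulum protein of B cells, 101 (37.8-fold, 1.53), and AIFM3, a relative of apoptosis-inducing factor, 100 (37.4-fold, 1.51). TMEM270, SPTY2D1, MANSC1, DKK3 and FAM161B had between 68 and 93 counts. Of the 10 lowest, LYZ, which encodes lysozyme, had 191 counts in shCtrl and 0 in shWBSCR22, at least 56.7-fold lower against the floor, with a log2 ratio of -1.51 at the upper bound of the wider interval. KCTD5, PDCD2L, CDH15, ZNF621, PDE7A, TMEM42, OTUD4 and PRELID2 had between 98 and 138 counts against 0. UTP15, a factor of small-subunit assembly, had 170 and 1 (log2 ratio -6.66, counting interval -12.56 to -4.75).

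Ranked by the wider interval instead, a ranking made after the values were seen, genes with counts in both libraries moved up. TMEM238, a small membrane protein, had 558 and 2620 counts (log2 ratio 2.40, 1.99 to 2.82), SLC29A4, a monoamine transporter, 180 and 861 (2.42, 1.70 to 3.20), and CLIC3, a chloride channel protein, 594 and 2155 (2.02, 1.61 to 2.45). Lowest was MPO, the myeloperoxidase of granulocyte precursors, with 692 and 21 (-4.84, -8.91 to -2.68). NOP16, a nucleolar factor of large-subunit assembly, had 2338 and 564 (-1.88, -2.42 to -1.39), and HSPA8, the constitutive cytosolic chaperone, 9894 and 3296 (-1.42, -1.63 to -1.21).

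Factors that build ribosomes were lower as a group in shWBSCR22. Of 54 measured small-subunit factors 1 was higher, 9 lower and 44 neither, and the median log2 ratio was -0.48 (-0.62 to -0.37), below all of the 10000 random lists. UTP20 (-1.93, -4.15 to -0.31), RRP9 (-1.34), DCAF13 (-1.09) and PDCD11 (-1.03), which process the precursor of ribosomal RNA, were among the 5 called lower with the wider interval. Of 48 large-subunit factors 0 were higher and 5 lower, with a median of -0.35 (-0.47 to -0.17) at percentile 0.030. NOP16 and PAK1IP1 (-1.67, -3.63 to -0.17) were among these. At a mean of at least 30 CPM the medians were -0.37 and -0.46. RNA polymerase I genes had a median of -0.30 over 16 members (percentile 5.17) and did not stand apart, with 2 lower, of which POLR1A, its largest subunit, had -1.13 (-1.78 to -0.53).

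Ribosomal proteins went both ways. The 44 measured large-subunit proteins had a median of -0.05 at percentile 1.21, or 24.3 when the random lists were also matched on GC content, and 1 was lower by the size rule, RPL30 (-1.17, -1.59 to -0.76). The wider interval lay above 0 for 14 of them, such as RPL22 (0.60, 0.43 to 0.77), and below 0 for 17, such as RPL7A (-0.54, -0.61 to -0.47). The 33 small-subunit proteins had a median of -0.03 (percentile 5.47), with a range of -0.12 to 0.03 over the alternative settings, and none was called. Their interval lay above 0 for 8 and below 0 for 9, among them RPS13 (-0.69, -0.88 to -0.51) and RPS18 (-0.54, -0.61 to -0.48). Both families have many near-identical pseudogenes, so their counts are uncertain. Mitochondrial ribosomal proteins had a median of -0.26 (-0.41 to -0.07) over 74 members at percentile 0.010. Of these 1 was higher and 8 lower, or 0 and 4 with the wider interval. The lower ones by either interval held MRPS22 (-2.25, -4.58 to -0.59) and MRPS26 (-1.64, -2.51 to -0.87). Among their 46 members of at least 30 CPM the median was -0.09 at percentile 5.59, so that list no longer stood apart there.

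Heat shock proteins had the lowest median of the ranked lists, -0.81 (-1.04 to -0.36) over 19 measured members, below all of the random lists, and also below them at 30 CPM or more (-0.80). Of these 0 were higher, 7 lower and 12 neither. HSPA8, HSPE1 (-1.08, -1.37 to -0.81), the co-chaperonin of mitochondria, BAG3 (-1.06, -2.00 to -0.22), a co-chaperone of HSP70, and CHORDC1 (-2.33, -4.81 to -0.61), which binds HSP90, were called lower with either interval. Proteasome subunits had a median of -0.28 (-0.43 to -0.10) over 30 members at percentile 0.070, with 0 higher and 3 lower; PSMC2, an ATPase of the regulatory particle, had -1.09 (-1.76 to -0.48). The messenger RNAs of the mitochondrial genome had a median of -0.26 (-0.67 to 0.07) over 13 members at percentile 0.41, or 4.84 when matched on GC content as well. Among them MT-ND6, a subunit of complex I, had 21077 and 10508 counts (-0.84, -0.96 to -0.72).

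**Figure D3:**
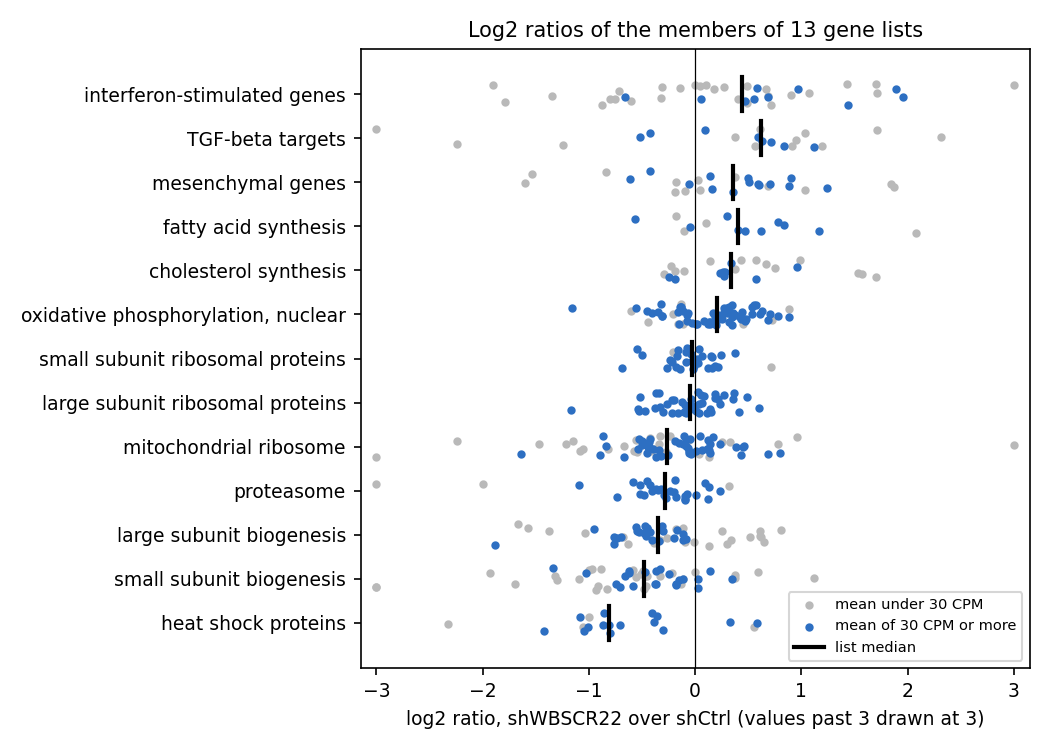
Log2 ratio of shWBSCR22 over shCtrl (horizontal axis) of each measured member of 13 of the gene lists, in blue with a mean of at least 30 CPM and in grey below it, with the list median as a black bar. Heat shock proteins had a median of -0.81 and interferon-stimulated genes 0.44.

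Other groups stood higher in shWBSCR22. Targets of transforming growth factor beta had a median of 0.62 (0.09 to 0.95) over 20 members at percentile 99.91. Of these 5 were higher and 3 lower, or 2 and 2 with the wider interval. CTGF, a matricellular protein, had 22 and 99 counts (2.31, 0.12 to 5.07), whereas BAMBI, a decoy receptor of the pathway, had 105 and 10 (-3.16, -10.93 to -0.08). Mesenchymal genes had a median of 0.35 (-0.09 to 0.68) over 27 members at percentile 99.27, with 4 higher and 2 lower, but percentile 87.0 when every gene with at least 1 count was taken in. Beside them the 4 measured fibroblast markers, among them COL1A1, which both lists hold, were all above 0, with a median of 1.10 (0.37 to 1.22 over the alternative settings). COL6A2, a collagen VI chain, was higher (1.87, 0.73 to 3.10) and TPM1, a tropomyosin, lower (-1.61, -2.54 to -0.78). Fatty acid synthesis genes had a median of 0.40 (-0.11 to 0.84) over 13 members at percentile 98.89, with 2 higher, ACSL1 (2.08, 0.24 to 4.23), which activates long-chain fatty acids, and SCD (1.16, 0.92 to 1.41), the stearoyl-CoA desaturase.

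Cholesterol synthesis and uptake genes had a median of 0.34 (0.14 to 0.66) over 23 members at percentile 99.05, with 3 higher and 0 lower. HMGCS1, an enzyme early in cholesterol synthesis, had 19 and 56 counts (1.70, -1.04 to 4.89), so that its wider interval held 0. At 30 CPM or more this list lay at percentile 91.0. Nuclear-encoded subunits of oxidative phosphorylation had a median of 0.20 (0.08 to 0.32) over 70 members at percentile 99.08, although 0 were called higher and 1 lower, SDHB of complex II (-1.16, -1.69 to -0.67). Replication-dependent histone genes, whose transcripts lack a poly(A) tail, had a median of 0.78 (0.25 to 1.53) over 16 members at percentile 99.20, with 6 higher and 0 lower. HIST1H2AE had 33 and 157 counts (2.40, 0.66 to 4.50), and the near-identical copies of this family make its counts uncertain. Glucocorticoid receptor targets had a median of 0.46 (-0.30 to 0.75) over 16 members at percentile 99.52, and at 30 CPM or more percentile 74.9. DUSP1, a phosphatase of MAP kinases, was higher (1.11, 0.46 to 1.76) and TGM2, a transglutaminase, lower (-1.29, -1.79 to -0.83). In all, 15 of 39 ranked lists stood apart, 7 low and 8 high, where 1.95 would be given by chance if the genes within a list varied independently of each other.

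Cell-cycle groups did not stand apart. Mitosis genes had a median of 0.10 over 33 members (percentile 80.2), with 1 higher and 2 lower, and DNA replication genes 0.06 over 39 (percentile 73.8), with 2 and 4. TTK, a spindle checkpoint kinase, was higher (2.34, 0.16 to 5.09). G1 cyclins, kinases and their inhibitors had a median of -0.18 over 16 members (percentile 18.5), with 1 higher and 2 lower, and lay at percentile 0.365 at a mean of at least 5 CPM but at 64.1, with a median of 0.11, at 30 CPM or more. CDK4, the G1 kinase, had 264 and 61 counts (-1.94, -3.89 to -0.47), and its partner CCND1, cyclin D1, 1098 and 488 (interval of the log2 ratio -1.60 to -0.44). The CDK inhibitor CDKN2A had 12740 and 6346 counts (-0.84, -0.998 to -0.684). Its mean of 603 CPM was the highest of this list. Whether that level is usual for the cell line named in the labels was not tested. Targets of p53 had a median of 0.13 over 26 members (percentile 80.3), with 4 higher and 3 lower, or 2 and 1 with the wider interval. BTG2, an antiproliferative factor, had 43 and 256 counts (2.73, 1.28 to 4.47). BCL2-family and death receptor genes had -0.02 over 29 (percentile 49.7), with 4 and 2, or 0 and 1 with the wider interval. TNFRSF10A, a TRAIL receptor, had -3.28 (-11.84 to -0.09).

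Stress and signalling groups also lay within the range of random lists. Unfolded protein and integrated stress genes had a median of 0.02 over 32 members (percentile 56.6), with 2 higher and 1 lower. NUPR1, a stress-induced chromatin protein, had 860 and 2493 counts (1.70, 1.34 to 2.07), and DDIT4, an inhibitor of mTORC1, 331 and 69 (-2.09, -3.88 to -0.71). NRF2 targets had -0.14 over 25 (percentile 10.4), with 1 and 2; FTH1, the ferritin heavy chain, was lower (-1.19, -1.52 to -0.88) and AKR1C1, an aldo-keto reductase, higher (1.26, 0.60 to 1.94). Immediate early and growth factor response genes had 0.29 over 33 (percentile 96.3), with 6 and 6, or 3 and 3 with the wider interval. They lay at percentile 99.73 at 30 CPM or more. NF-kB dependent cytokine genes had -0.02 over 14 (percentile 51.0), with 2 and 2, among them the chemokine CCL5 at 104 and 392 counts (2.08, 1.07 to 3.16). MHC class I genes had 0.09 over 18 (percentile 63.6), with 1 and 1; HLA-F had 1.02 (0.44 to 1.60), uncertain because HLA genes share reads. YAP and TEAD targets had -0.31 over 16 (percentile 11.9), with 2 and 1, and small RNA processing genes 0.06 over 12 (percentile 67.3), with 1 and 1.

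Hypoxia and glycolysis genes had a median of 0.11 over 34 members (percentile 80.1), with 3 higher and 1 lower. ENO2, a glycolytic enolase, was higher (1.20, 0.85 to 1.55). Autophagy and lysosome genes had 0.19 over 36 (percentile 96.9), with 1 and 3, and lay at percentile 98.22 when also matched on GC content. Invasion proteases and receptors had 0.25 over 26 (percentile 93.4), with 5 and 1, and epithelial adhesion genes 0.11 over 18 (percentile 64.8), with 1 and 1. TRMT112 and the methyltransferases that bind it, a list that holds the targeted BUD23 itself and whose median is the value of TRMT112, had -0.56 over 7 (percentile 2.73), with 0 and 1, and stood apart when also matched on GC content (percentile 2.17) and with the deposited FPKM and a pseudocount of 0.1 (percentile 1.98). Genes near BUD23 in the Williams-Beuren region had 0.04 over 20 (percentile 68.8), with 2 and 2; LAT2 had 130 and 11 counts (-3.34, -10.45 to -0.40). Common reference genes had -0.03 over 17 (percentile 24.6) and -0.11 to 0.05 over the alternative settings. Among them GAPDH had -0.83 (-0.93 to -0.74) and ACTB -0.65 (-0.71 to -0.59). Metallothioneins, 4 measured, had a median of 0.11, which ran from -0.45 to 0.14 over the alternative settings. The abundant MT1E had -0.86 (-1.08 to -0.65) and MT2A -0.43 (-0.56 to -0.30). The less abundant MT1X had 0.75 (0.15 to 1.35) and MT1F 0.64 (-0.93 to 2.14). The medians of G1, DNA replication, integrated stress, immediate early, small RNA, Williams-Beuren and YAP genes also took both signs over those settings.

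Markers of other cell types were few. Ductal markers had a median of 0.53 over 8 members (percentile 94.0; 0.15 to 0.98 over the alternative settings), with 2 higher, and S100P, a calcium-binding protein of pancreatic carcinoma, had 3523 and 8077 counts (1.36, 1.18 to 1.55). Leukocyte markers had -0.36 over 5 (percentile 27.6), from -3.87 to -0.22 over those settings, with 2 lower, LYZ and CORO1A, and lay at percentile 1.27 when every gene with at least 1 count was taken in. Lists with under 5 measured members were not ranked. Of the fibroblast markers, COL1A1, a collagen I chain, had 839 and 1768 counts (1.24, 0.85 to 1.63) and DCN, a matrix proteoglycan, 10 and 44 (2.25, -1.18 to 7.16). The endothelial markers, 3 measured, had a median of 0.62 (0.14 to 0.63 over those settings). Endocrine markers, 3 measured, had 0.06 (-0.08 to 0.11), with PAX6, an endocrine transcription factor, at 6 and 92 counts (interval of the log2 ratio 0.80 to 11.13). Of the acinar markers 2 were measured, the protease CTRC at 0 and 52 counts, at least 19.4-fold higher against the floor with a lower bound of 0.15 by the wider interval, and CEL at 39 and 46; their median was 3.64, or 2.34 with CTRC at its bound, and 0.57 to 3.65 over those settings.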

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

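In the following, the tests of counting error, of read clusters, of genes with low counts and of myeloid genes against random genes were chosen only after the result was seen. Counts that were high in one library and absent in the other formed the first pattern, with 210 genes having at least 41 counts in one library and 0 in the other, where Poisson counting at this depth would give 1.34e-14. Counting error therefore cannot account for them. Many reads from each of few fragments, as amplification of little material gives, remain a candidate explanation: the number of genes per count peaked at 8 reads in shCtrl and 15 in shWBSCR22, with fewer genes at 1 or 2 reads (197 against 283 per count in shCtrl, 143 against 202 in shWBSCR22). The wider interval excluded 0 for 72 of the 210. With that interval widened again for the 12980 genes searched, 1 of the 210 kept a bound away from 0, USH1C at 1.27. For that gene this argues only against clusters of 8 and 15 reads. The interval takes every fragment of a library to give the same number of reads. Larger clusters are not excluded for USH1C, and the explanation stays open for the others. No biological explanation was tested for them as a set.

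The interferon-stimulated genes formed the second pattern. Their higher median was not removed by matching random lists on GC content (percentile 99.88) or by keeping members of at least 30 CPM (99.93). This argues against GC content and low counts as the whole cause. Without ISG15 the percentile was 99.745, but 1 of 38 members can hardly move a median. Leaving it out therefore could not decide whether ISG15 alone was the cause. An effect of the knockdown remains a hypothesis, because with 1 library per group it cannot be told apart from an effect of the shRNA or culture rather than the knockdown, such as a response to the hairpin itself. STAT2, a transcription factor of the type I interferon response, had 376 counts in shCtrl and 360 in shWBSCR22 (log2 ratio after scaling 0.10, -0.67 to 0.84).

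MPO and LYZ, with 692 and 191 counts in shCtrl and 21 and 0 in shWBSCR22, formed the third pattern. For MPO, clusters of 8 and 15 reads are argued against. Its wider interval, widened again for the 12980 genes searched, had an upper bound of -1.14, though larger clusters are not excluded. For LYZ that bound was 0.63, and many reads from each of few fragments stay an open explanation. Reads from blood cells in the shCtrl library are not decided: of 30 further myeloid genes 21 had counts, and 15 (71.4%) were higher in shCtrl, where random genes of the same expression gave 55.8% on average and the share lay at their percentile 92.2. Of other genes noticed with MPO and LYZ, ARHGDIB, PRSS57 and TRH had 83, 82 and 92 counts against 0, while PRTN3, a neutrophil protease, had 455 and 1585, and ELANE, of the 21 genes tested, had 244 and 175. No biological explanation was tested.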

How the results depend on the processing

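No paired analysis was possible because each group held 1 library, which also leaves no library to omit. The alternatives marked here as added were chosen after seeing the data, and the FPKM alternatives have no interval. BUD23 had a log2 ratio of -0.80 with total-count scaling and -0.80 with FPKM and a pseudocount of 0.1, and no alternative brought it to -1. ISG15 had 1.87 with total counts, 1.87 and 1.86 with FPKM and pseudocounts of 0.1 and 1, and 1.83 less the median of its GC bin (added). Genes higher and lower numbered 2863 and 3816 over every gene with at least 1 count, 597 and 559 at 5 CPM, 2730 and 2737 at a ratio of 1.5, 841 and 813 with the interval bound itself past a log2 ratio of 1, and 520 and 455 with FPKM and a pseudocount of 1. The added alternatives gave 544 and 387 with the wider interval, and 114 and 75 at 30 CPM with scaling recomputed there. Fewer genes entered under the stricter filters, and otherwise the cause was not tested. Total-count scaling shared 2979 of its 3180 calls with the main setting. The median of all genes lay at -0.02 with TMM and -0.10 with total counts. Between 12 and 16 of the ranked lists stood apart under the 10 alternatives run for them. The interferon list kept a positive median, from 0.13 to 0.61. No list that stood apart changed sign. No called gene among those selected by the naming rule did so either. For the genes this says little, since their ratios were at least 1 in size and rescaling shifted all genes only slightly. The main results were BUD23, ISG15, the interferon list and the counts of genes and lists. Of their recomputed values 41 stayed and 20 moved, a count being said to move past a ratio of 1.5. For the other selected genes and lists 1458 values stayed within their intervals and 298 moved past them or had none.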

Other observations

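Genes next to ISG15 on chromosome 1 were looked at after its value was seen. HES4, a transcriptional repressor of the Notch pathway at 998962 to 1000172, the next protein-coding gene, had 2643 and 7565 counts in shCtrl and shWBSCR22 (log2 ratio 1.68, 1.48 to 1.89). SAMD11 had 1.12 (0.35 to 1.89) and C1QTNF12 1.19 (0.37 to 2.02), while AGRN had -0.01 (-0.39 to 0.35), NOC2L -0.52 (-1.04 to -0.04) and UBE2J2 -0.48 (-0.79 to -0.18). Genes with the highest GC content tended to be higher in shWBSCR22: among genes of at least 30 CPM the fifth with the highest GC content had a median log2 ratio of 0.16 and the fifth with the lowest -0.06. HES4, with 74.2% GC, lies at the upper end of that range.

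Growth factor response genes, chosen here after their values were seen, went both ways. ETV5 and DUSP4, a transcription factor and a phosphatase induced by ERK signalling, had log2 ratios of -1.31 (-2.52 to -0.27) and -1.85 (-3.56 to -0.51), and PHLDA1 had -1.41 (-3.10 to -0.05). ETV4 had -0.77 (-1.07 to -0.48) and FOSL1 -0.77 (-1.52 to -0.09). The immediate early genes IER2 and EGR1 were higher, at 1.28 (1.07 to 1.49) and 1.41 (0.24 to 2.62), and JUNB had 0.83 (0.35 to 1.31). Of the heat shock list, HSPB1 had 0.33 (0.28 to 0.38) and HSPA4L 0.56 (-0.56 to 1.64), and the near-identical pair HSPA1A and HSPA1B, whose reads can be shared, had 0.58 and -0.86.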
